A study of Mus musculus with 11 samples.

How the data were processed

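Gene and transcript tables covered 11 libraries of mouse OT-I CD8+ T cells at 12 h. The values are estimated counts, used as deposited by the authors, whose notes name StringTie, a tool that estimates counts from coverage. Per the submitters' processing notes, the genome build was mm39 and the tools were STAR 2.7.1a, SAMtools 1.9, StringTie 2.1.0, R 4.0.5 and DESeq2 1.30.1, listed without their roles. Libraries were made with a SMARTer ultra-low input poly(A) kit per the labels. There were 55414 genes and 142435 transcripts, all in whole numbers, so nothing was rounded. Totals per library were equal between both tables in all 11 libraries, and at least 99.49% of genes equalled the sum of their transcripts. Totals ranged from 241.9e6 to 405.9e6, a ratio of 1.68. They exceed usual read numbers for a reason the labels do not state, and whether this affects the spread that the tests estimate was not tested. Precision was taken from the spread between libraries alone. Unused columns numbered 0 in both tables.

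Names, transcript types and exon lengths came from GENCODE M21, which is built on GRCm38, while the tables are on mm39, so identifiers were matched without version and no coordinates are given. In all, 52081 genes (94.0%, holding at least 98.6% of counts) received a symbol and 138292 transcripts (97.1%, at least 99.2% of counts) were matched. Libraries were grouped by treatment as labelled: naive (n = 4), stimulated (n = 4) and Torin (n = 3). The replicate numbers, and the prefixes A, B and S of the descriptions, are not explained in the labels. Deviations of log2 CPM from the group mean of each gene were correlated between libraries of the same number. These deviations correlated above 0.1 in each pair of stimulated and naive libraries (0.16, 0.23, 0.15 and 0.29 for numbers 1 to 4). The same held for Torin and stimulated libraries (0.11, 0.15 and 0.31), but not for each pair of Torin and naive libraries (0.08, 0.13 and 0.28). The highest correlations with a library of another number lay between -0.1 and 0.07. Fits without a block were kept and the number was tried as a block. No pair of libraries was a duplicate, with a lowest chi-square per gene of 290.6 (Torin 1 and Torin 3).

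Genes were tested with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood F tests, with TMM composition factors, all 11 libraries in 1 model of group means, and the filterByExpr filter at a minimum count of 10, which left 22238 genes. The common biological coefficient of variation was 0.79. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. Principal components used the 2000 most variable genes on log2 CPM with a prior count of 2. The 37 gene lists, fixed before the data were examined as were comparisons and tests, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with at least 5 measured members. Camera with an estimated correlation and fry were run beside it. Members were also adjusted over their list alone. Named genes were chosen by rule. In each comparison these were the 8 largest rises and 8 largest falls among genes past the threshold with an absolute log2 change of at least 1, at least 10 CPM in the higher group and no overlap between libraries. Predicted genes and receptor or immunoglobulin segments were excluded. The 2 largest rises and 2 largest falls per list and 28 fixed genes were added. Values per library of Igkc, Xist and some other genes were looked up after the data were seen.

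The poison exon share was the share of Tra2b counts in transcripts with an internal exon inside the first coding intron (10623 nt). Shares were compared by exact permutation of library labels, as was the share in decay-annotated or retained-intron transcripts of SR genes. Transcript usage was tested with diffSpliceDGE and Simes p-values in 10224 genes, and with limma on log2 transcript ratios with a prior of 0.5 CPM. Usage genes named were Ptprc, Tra2b and, per comparison, the 8 with the smallest p, leaving out genes with placeholder symbols such as Gm or Rik names. Because both main comparisons share the stimulated libraries, their correlation was also computed with these libraries split (6 ordered splits) and in 20 data sets simulated with no effect.

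The steps were tested on simulated data. With 100 genes changed among 21527 (stimulated against naive) or 21544 (Torin against stimulated), edgeR recovered 10% and 11% at 2-fold and 72% and 71% at 4-fold, with 2 and 3 false calls. Camera recovered a list raised 1.5-fold in both designs, with 1 and 0 false calls among lists. Genes were drawn independently in these simulated data, so false calls from correlated list members were not tested. With transcripts exchanged in 200 of 10224 genes, diffSpliceDGE recovered 40.5% and 36% with 72 and 75 false calls, and limma on ratios 71.5% and 67.5% with 5 and 8. Alternatives were DESeq2 1.42.0 size factors, library totals alone, no filter, a mean CPM of at least 5, the replicate block, the description prefix, a change tested against 0.5 on the log2 scale, DESeq2, limma-voom, only the libraries compared, each library left out, and stricter transcript filters (10 counts in 3 libraries and 5% of the gene). Removal of all libraries of each number, removal of the 2 genes at 0 in exactly 1 library of an otherwise high group, the limma ratio test, and library totals for summed Tra2b transcripts were chosen after seeing the data. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9. Raw reads were not used here, and a Torin library of number 2 was not analysed here.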

Results

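RNA was sequenced from OT-I CD8+ T cells, mouse cells that carry a transgenic T cell receptor for an ovalbumin peptide. At 12 h, 4 naive libraries came from untreated cells and 4 stimulated libraries from cells given DMSO, the solvent, and N4, the stimulating peptide. A further 3 Torin libraries came from cells given N4 with Torin, an inhibitor of the kinase mTOR. Replicate numbers run from 1 to 4 in each group, with Torin libraries of numbers 1, 3 and 4. Estimated counts were given for 55414 genes and 142435 transcripts. Totals, given in units of 10 to the power 6 estimated counts, were 347.9, 243.3, 241.9 and 305.5 in naive 1 to 4 and 279.0, 318.6, 286.1 and 306.9 in stimulated 1 to 4. They were 274.5, 315.0 and 405.9 in Torin 1, 3 and 4. These totals of estimated counts exceed usual read numbers, for a reason the labels do not state, so no counting interval was computed from them. Within groups, log2 CPM (counts scaled to library size) of library pairs correlated at r of 0.902 to 0.936 (naive), 0.921 to 0.933 (stimulated) and 0.924 to 0.942 (Torin) across genes. The first principal component held 39.1% of the variance and separated naive from the other libraries. The next component held 17.5% and set the libraries of number 4 apart. The labels do not say whether libraries came from separate animals, so p-values measure only the spread between samples. Xist stood at 27 to 45.7 CPM in the libraries of number 3 and at most 0.611 CPM elsewhere. Igkc stood at 13100 to 46900 CPM in those of number 4 and at most 16.9 CPM elsewhere. Libraries of these numbers thus shared traits of their source across groups, and the main tests do not pair them.

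The first comparison asked what N4 stimulation changed relative to naive cells. Ifng, which encodes interferon gamma, rose from 64.0 ± 87.8 to 3199 ± 950 CPM (mean ± SD, n = 4 each; log2 change 5.64, SE 1.302, adjusted p = 0.00514). Il2, the gene of interleukin 2, rose from 10.1 ± 11.5 to 381 ± 114 CPM, and Gzmb, a cytotoxic granule protease, from 15.8 ± 20.2 to 807 ± 608 CPM. Il2ra, the high-affinity interleukin 2 receptor chain, rose from 8.17 ± 8.25 to 194 ± 20.6 CPM (log2 change 4.57, SE 0.67, adjusted p = 0.000283). Myc, a growth-promoting transcription factor, rose from 30.1 ± 15.8 to 257 ± 14.2 CPM. Genes of resting T cells fell, among them the interleukin 7 receptor gene Il7r, from 125 ± 30.9 to 4.09 ± 3.48 CPM, and the transcription factor gene Tcf7, from 248 ± 64.3 to 29.4 ± 20.5 CPM. Klf2, which maintains quiescence, fell from 640.0 ± 124 to 18.8 ± 31.5 CPM, with 66.0 CPM in stimulated 1 and at most 3.47 CPM in the other stimulated libraries.

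Among the largest rises were the chemokine gene Ccl1, from 3.34 ± 4.85 to 255 ± 294 CPM, the retinoic acid binding protein gene Crabp2, from 11.4 ± 15.7 to 786 ± 679 CPM, and the ubiquitin-like gene Ubd, from 3.44 ± 3.44 to 202 ± 80.4 CPM. The near-identical paralogs Sprr2a1, Sprr2a2 and Sprr2a3 also passed, with log2 changes of 6.38, 6.38 and 6.84, but which of these paralogs the reads came from is uncertain. Among the largest falls were Ifngas1, a noncoding RNA gene beside Ifng, from 53.4 ± 29.2 to 0.55 ± 0.72 CPM, and the T cell surface gene Cd7, from 483 ± 223 to 7.01 ± 12.1 CPM. Cd8b1 fell by 1.22 on the log2 scale and Cd3e by 0.88, while Cd8a had a log2 change of -0.07 (adjusted p = 0.893). Total Tra2b, the splicing factor gene named in the series title, stood at 100 ± 9.69 CPM in naive and 125 ± 17.2 CPM in stimulated cells (log2 change 0.32, adjusted p = 0.0733). With library totals alone the change of Tra2b, stimulated versus naive, was -0.19 (adjusted p = 0.261), so its direction depended on the scaling. Its call began without stimulated 1 (0.38), stimulated 3 (0.32) or Torin 4 (0.41). Mtor rose from 7.06 ± 0.97 to 13.1 ± 2.07 CPM.

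Of 22238 genes tested, 8773 changed, 4272 higher and 4501 lower, and 3176 and 3602 of these changed at least 2-fold. Directions were taken after composition factors, under which the median log2 change of all genes was -0.22. With library totals alone that median was -0.71 and 28.5% of changed genes were higher, against 48.7%. No single library moved the count by over 1.5 times.

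**Figure D1:**
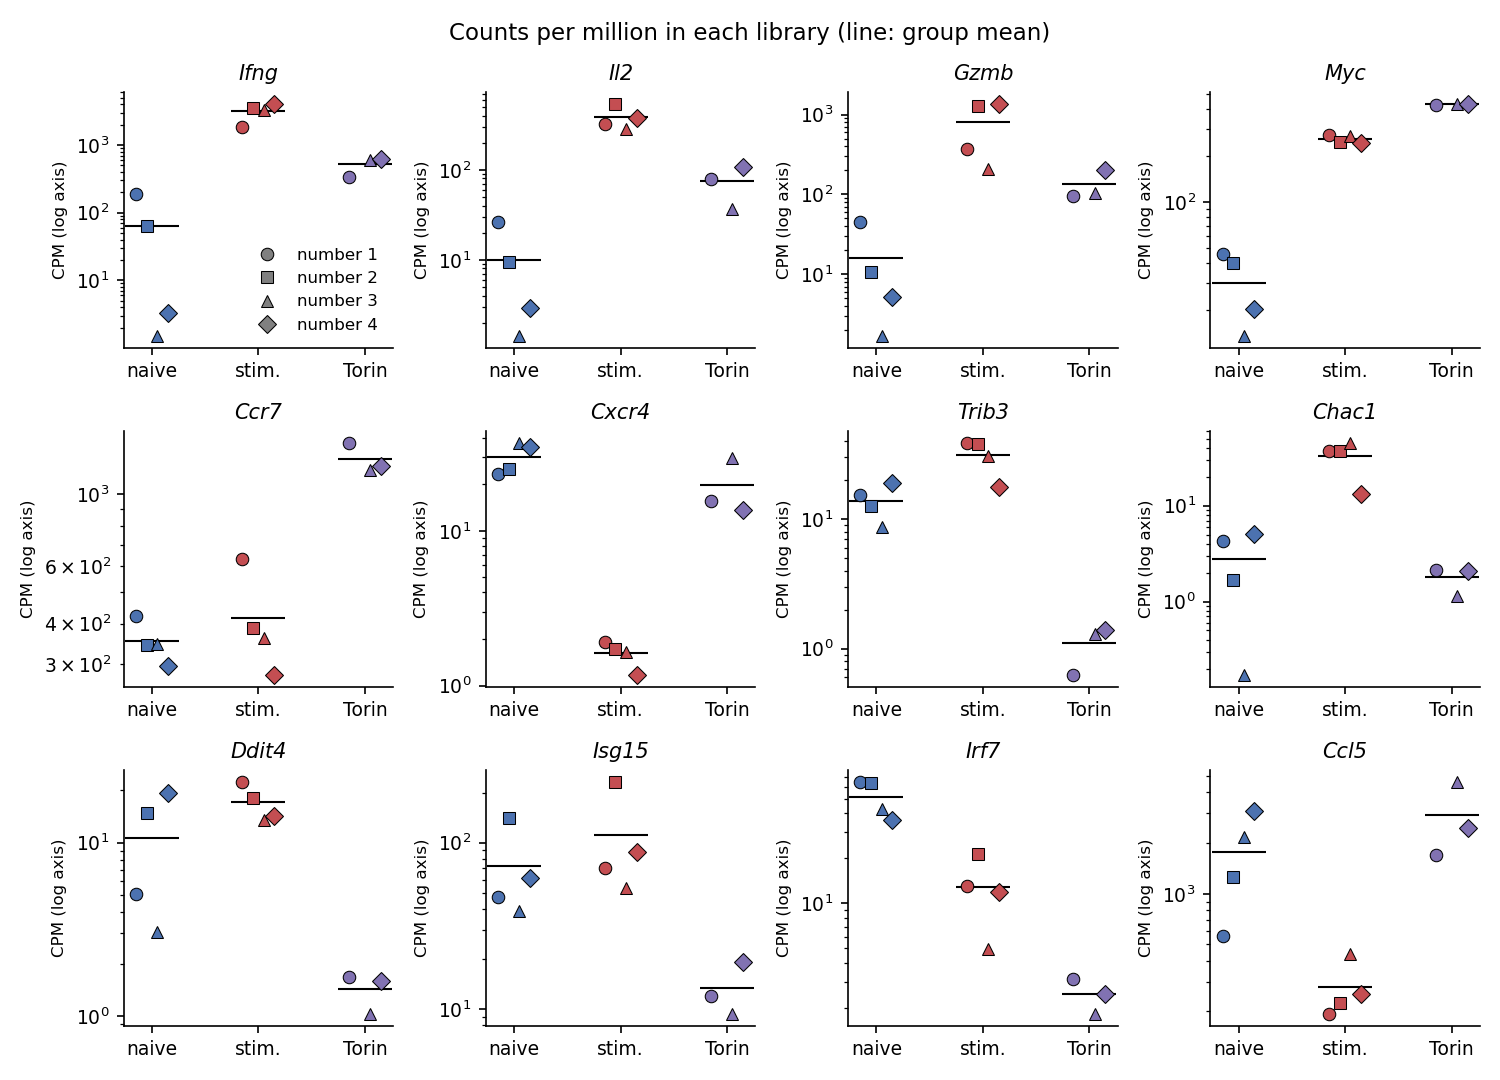
CPM (log axis) of 12 genes in each library, by group, with 1 point per library marked by its replicate number and a line at the group mean. Ifng lies between 1860 and 4100 CPM in stimulated libraries and at 189 CPM in naive 1, against 1.5 CPM in naive 3.

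Of the 37 gene lists, 21 were past the threshold in stimulated against naive cells by camera, 17 higher and 4 lower, and 0 with an estimated correlation, where the lowest adjusted p was 0.126. Fry, which tests each list on its own, called 23. Among 22 activation genes of the T cell receptor response, 13 rose, 1 fell and 8 were not past the threshold (14, 1 and 7 adjusted over the list alone; camera adjusted p = 8.07e-08; adjusted p = 0.126 with an estimated correlation). Nr4a1, an immediate target of receptor signalling, rose from 13.8 ± 14.7 to 130 ± 30.9 CPM, and Irf4 from 3.77 ± 2.89 to 69.4 ± 14.7 CPM. Of 22 effector genes 16 rose, with the same count over the list alone (camera adjusted p = 2.83e-06; adjusted p = 0.126 with an estimated correlation). Naive 1 held more of these transcripts than the other naive libraries, with Ifng at 189 CPM and Gzmb at 45.6 CPM, against 62.6 and 10.6 CPM in naive 2, 1.5 and 1.68 CPM in naive 3, and 3.34 and 5.16 CPM in naive 4. Of 15 genes of inhibitory receptors and exhaustion, 7 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.00237; adjusted p = 0.233 with an estimated correlation). Lag3 rose from 4.77 ± 4.48 to 90.9 ± 22.3 CPM, while Tox and Socs3 fell.

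Of 34 ribosome biogenesis genes, 33 rose and 1 was not past the threshold (34 rose adjusted over the list alone; camera adjusted p = 2.5e-33; adjusted p = 0.126 with an estimated correlation). Rrp12 rose from 2.35 ± 0.97 to 20.5 ± 0.15 CPM and Mybbp1a from 8.60 ± 4.50 to 72 ± 3.57 CPM. Of 20 cytosolic aminoacyl-tRNA synthetase genes, which load amino acids onto tRNA, 18 rose, also over the list alone (camera adjusted p = 2.5e-15; adjusted p = 0.126 with an estimated correlation). Nars rose from 37.1 ± 11.3 to 196 ± 28.9 CPM. Translation factors had 21 members that rose and 2 that fell of 26 (22 and 2 adjusted over the list alone; camera adjusted p = 3.39e-10; adjusted p = 0.126 with an estimated correlation), with Eif2s2 at 78.0 ± 10.7 and 390 ± 68.1 CPM. Cytosolic ribosomal protein genes had 31 of 40 that rose (34 rose and 1 fell adjusted over the list alone; camera adjusted p = 6.15e-08; adjusted p = 0.422 with an estimated correlation), and their median log2 change was 0.70, or 0.21 with library totals alone. Amino acid transporter genes had 7 of 12 that rose and 1 that fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.000316; adjusted p = 0.156 with an estimated correlation). Slc7a5, which imports large neutral amino acids, rose from 9.02 ± 1.83 to 90.8 ± 19.4 CPM.

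Of 23 genes controlled by ATF4 or used in serine and one-carbon metabolism, 16 rose (17 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.96e-07; adjusted p = 0.158 with an estimated correlation). Mthfd2, a mitochondrial one-carbon enzyme, rose from 12.9 ± 6.36 to 140 ± 35.6 CPM and Asns, which makes asparagine, from 2.04 ± 1.78 to 37.5 ± 12.5 CPM. Of 29 nuclear oxidative phosphorylation genes 24 rose (25 adjusted over the list alone; camera adjusted p = 1.94e-08; adjusted p = 0.126 with an estimated correlation), and of 24 genes of the mitochondrial ribosome and import 21 rose, also over the list alone (camera adjusted p = 1.79e-14; adjusted p = 0.126 with an estimated correlation). The chaperonin gene Hspe1 rose from 312 ± 146 to 4794 ± 617 CPM. Glycolysis had 11 of 21 measured members that rose and 1 that fell (13 and 3 adjusted over the list alone; camera adjusted p = 0.000295; adjusted p = 0.443 with an estimated correlation). Hk2, a hexokinase, rose from 7.83 ± 4.02 to 62.9 ± 9.87 CPM, while the glucose transporter gene Slc2a1 had a log2 change of 0.65 (adjusted p = 0.0719), which passed without naive 2 (0.91). Cholesterol synthesis had 14 of 23 that rose and 1 that fell (15 and 1 adjusted over the list alone; camera adjusted p = 0.00013; adjusted p = 0.487 with an estimated correlation), with Idi1 at 5.18 ± 3.17 and 56.6 ± 2.58 CPM.

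Of 36 genes of G1/S and DNA replication, 20 rose and 2 fell (25 and 3 adjusted over the list alone; camera adjusted p = 1.2e-05; adjusted p = 0.291 with an estimated correlation). Cyclin D2 (Ccnd2) rose from 130 ± 36.7 to 809 ± 87.1 CPM and cyclin D3 (Ccnd3) fell from 177 ± 28.6 to 78.8 ± 10.1 CPM. Mitosis genes had 1 member that rose and 3 that fell of 22 (camera adjusted p = 0.472), and Mki67 stood at 2.21 ± 1.10 and 1.36 ± 1.16 CPM. Of 18 genes of the unfolded protein response, 11 rose and 2 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.00924; adjusted p = 0.57 with an estimated correlation), but with library totals alone (median log2 change 0.32) or a mean CPM of at least 5 the list was no longer past the threshold. Heat-shock and dissociation genes, listed as a check of sample handling, had 6 of 13 that rose and 1 that fell, also over the list alone (camera adjusted p = 0.000597, and adjusted p = 0.137 with an estimated correlation). Their summed level was 1010 CPM in naive, 4388 CPM in stimulated and 3293 CPM in Torin libraries. Whether handling or stimulation raised them was not tested.

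Naive and quiescence genes had 17 of 22 that fell, also over the list alone (camera adjusted p = 2.3e-11; adjusted p = 0.137 with an estimated correlation). Of 20 genes activated by FOXO factors, 17 fell and 1 rose, also over the list alone (camera adjusted p = 3.25e-09; adjusted p = 0.126 with an estimated correlation). Of 29 lysosome and autophagy genes, 17 fell and 1 rose, also over the list alone (camera adjusted p = 0.000495; adjusted p = 0.383 with an estimated correlation). The protease gene Ctsd fell from 307 ± 77.4 to 55.2 ± 20.7 CPM, and Gabarapl1 rose from 27.3 ± 6.59 to 61.4 ± 5.58 CPM. Type I interferon-stimulated genes had 8 of 20 that fell and 1 that rose, also over the list alone (camera adjusted p = 0.0362; adjusted p = 0.672 with an estimated correlation). The antiviral membrane gene Bst2 was the 1 that rose, from 218 ± 62.1 to 515 ± 120 CPM. That list's call ended with a mean CPM of at least 5, without the libraries of number 1, and without naive 2 (median -0.89), stimulated 1 (-0.93) or stimulated 3 (-0.77). Lists that were not past the threshold were fatty acid synthesis (4 rose and 4 fell of 14), hypoxia response (7 and 4 of 18), p53 and apoptosis (7 and 5 of 17), mTOR pathway components (7 and 8 of 22) and mitochondrially encoded transcripts (4 and 0 of 15). The call for mitochondrially encoded transcripts began without naive 2 (median 0.59) or stimulated 1 (0.64).

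Transcripts of other cell types lay apart in single libraries. Summed granulocyte markers reached 8831 CPM in naive 2 and 2104 CPM in stimulated 2, and at most 254 CPM elsewhere, and monocyte and macrophage markers reached 5123 CPM in naive 2. A fall of Lyz1, a lysozyme gene of myeloid cells, from 16.8 ± 25.8 to 0.36 ± 0.36 CPM, was seen in each number, with naive levels of 3.15, 55.4, 2.91 and 5.55 CPM in numbers 1 to 4. The immunoglobulin gene Igkc stood at 46900 CPM in naive 4, 14300 in stimulated 4 and 13100 in Torin 4, and at most 16.9 CPM elsewhere. No list of other cell types passed in stimulated against naive cells. Of their measured members, 3 of 12 B cell, 5 of 18 monocyte and macrophage, 3 of 12 granulocyte, 4 of 11 erythroid and platelet, 4 of 11 NK, gamma-delta and invariant T cell, and 1 of 7 stromal and endothelial markers fell, and none of these rose. Dendritic cell and antigen presentation markers had 1 that rose and 5 that fell of 14, and CD4 and regulatory T cell markers 2 and 1 of 7. With the replicate number as a block, the B cell (adjusted p = 0.0213), monocyte and macrophage (adjusted p = 0.0015) and granulocyte lists passed as lower. Without 1 library, calls of lower levels began for the B cell list (stimulated 4, median -2.63), the granulocyte list (naive 3, -3.24, and stimulated 2, -6.08) and the monocyte and macrophage list (naive 3, -2.70, and stimulated 2, -3.28).

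The second comparison asked what Torin changed in stimulated cells. Trib3, a pseudokinase gene induced by ATF4, fell from 31.3 ± 9.86 in stimulated (n = 4) to 1.11 ± 0.42 CPM in Torin libraries (n = 3; log2 change -4.82, SE 0.44, adjusted p = 0.000944). Sesn2, a stress-induced restrainer of mTOR complex 1, fell from 19.4 ± 4.93 to 1.52 ± 0.73 CPM, and Ddit4, also a restrainer of that complex, from 17.1 ± 4.13 to 1.44 ± 0.35 CPM. The chemokine receptor gene Cxcr4 rose from 1.61 ± 0.31 to 19.7 ± 8.85 CPM (log2 change 3.61, SE 0.31, adjusted p = 0.000944) and the chemokine gene Ccl5 from 278 ± 110 to 2938 ± 1527 CPM. Myb, a transcription factor, rose from 1.83 ± 0.81 to 15.3 ± 4.49 CPM, Ms4a4c from 74.0 ± 32.8 to 456 ± 34.6 CPM, and the p53 target Trp53inp1 from 8.02 ± 2.98 to 47.2 ± 6.41 CPM. Ccr7, which guides T cells to lymph nodes, rose from 416 ± 153 to 1285 ± 136 CPM. Eif4ebp1, a translation repressor that mTOR phosphorylates, fell from 676 ± 177 to 136 ± 8.49 CPM, and the perforin gene Prf1 from 58.3 ± 28.3 to 8.10 ± 1.70 CPM. The calls for Ccl5 without Torin 3 (2.91) and Ddit4 without Torin 1 (-3.70) or Torin 3 (-3.39) ended.

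Ifng, Il2 and Gzmb had lower means in Torin libraries without passing the test, with Ifng at 519 ± 160 against 3199 ± 950 CPM (log2 change -2.62, adjusted p = 0.278), Il2 at 74.2 ± 35.1 against 381 ± 114 CPM (-2.36, adjusted p = 0.149) and Gzmb at 134 ± 59.4 against 807 ± 608 CPM (-2.59, adjusted p = 0.195). The test took 1 spread per gene over all 11 libraries, naive ones included, and Ifng ranged from 1.5 to 189 CPM among naive libraries. A missed call is thus no evidence of no change. Ifng and Il2 passed when only the libraries of both groups were fitted, and Il2 and Gzmb by DESeq2. In numbers 1, 3 and 4 Ifng, Il2 and Gzmb were each lower with Torin, and the groups did not overlap. Ifng stood at 336 against 1863, 593 against 3320 and 628 against 4096 CPM. Myc stood at 433 ± 4.09 against 257 ± 14.2 CPM (0.75, adjusted p = 0.248), and it passed with only the libraries of both groups. Il2ra, at 190 ± 23.9 against 194 ± 20.6 CPM, had a log2 change of -0.03 (SE 0.62, adjusted p = 0.993). Total Tra2b stood at 151 ± 4.73 against 125 ± 17.2 CPM (0.27, adjusted p = 0.303).

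With Torin, 1027 of 22238 genes changed, 515 higher and 512 lower, 339 of each at least 2-fold. With library totals alone 67.6% of changed genes were higher, against 50.1%, and the median log2 change of all genes was 0.11, against -0.02. The count was 144 without Torin 3, 261 without Torin 1, 441 without stimulated 4, 463 without stimulated 2 and 541 without Torin 4. It was 656 without the low-count filter, 675 with the description prefix as a factor, 159 when a change above 0.5 on the log2 scale was tested, and 2970 by DESeq2. With the replicate block it was 965, of which 737 were among the 1027.

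In Torin against stimulated cells 16 of 37 lists were past the threshold by camera, 3 higher and 13 lower, and 0 with an estimated correlation (lowest adjusted p = 0.0905). Fry called 4. Of 23 ATF4, serine and one-carbon genes, 11 fell and 12 were not past the threshold (19 fell adjusted over the list alone; camera adjusted p = 2.89e-24; adjusted p = 0.0905 with an estimated correlation). Mthfd2, which just missed the threshold, stood at 48.7 ± 7.71 against 140 ± 35.6 CPM (-1.53, adjusted p = 0.0541) and passed without naive 1 (-1.53) or naive 3 (-1.53). Glycolysis had 10 of 21 that fell (17 adjusted over the list alone; camera adjusted p = 2.56e-16; adjusted p = 0.317 with an estimated correlation). The values of Hk2 (-0.76, adjusted p = 0.353) and Slc2a1 (-0.98, adjusted p = 0.0827) were not past the threshold, with calls that began without naive 3 for Hk2 (-0.76) and without naive 2 for Slc2a1 (-0.98). Of 20 aminoacyl-tRNA synthetase genes 6 fell (11 adjusted over the list alone; camera adjusted p = 1.84e-09; adjusted p = 0.436 with an estimated correlation), with Nars at 62.1 ± 4.18 against 196 ± 28.9 CPM. Slc7a5 fell from 90.8 ± 19.4 to 31.1 ± 1.49 CPM, the 1 member of 12 amino acid transporters past the threshold. Slc7a3 was lower without passing, at 1.55 to 2.24 CPM in Torin against 20.35 to 43.56 CPM in stimulated libraries. So was Slc1a4, at 1.5 to 2.21 against 3.77 to 11.82 CPM, and 0 members rose past the threshold. The transporter list was not past the threshold (camera adjusted p = 0.168), and its call began without naive 3 (median -0.14).

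Of 18 hypoxia-response genes 5 fell and 1 rose (10 and 3 adjusted over the list alone; camera adjusted p = 0.000113; adjusted p = 0.436 with an estimated correlation). Vegfa, an angiogenic growth factor gene, fell from 10.3 ± 3.23 to 0.91 ± 0.61 CPM, a call that ended without Torin 3 (-3.26) or Torin 4 (-3.22). Type I interferon-stimulated genes had 9 of 20 that fell (14 fell and 1 rose adjusted over the list alone; camera adjusted p = 5.56e-14; adjusted p = 0.317 with an estimated correlation). Ifit1 fell from 3.55 ± 2.65 to 0.26 ± 0.22 CPM, a call that ended without Torin 1 (-3.43) or Torin 4 (-3.47). Oxidative phosphorylation had 5 of 29 that fell (7 adjusted over the list alone; camera adjusted p = 0.000208; adjusted p = 0.436 with an estimated correlation). Cholesterol synthesis had 3 of 23 that fell (4 adjusted over the list alone; camera adjusted p = 9.42e-05; adjusted p = 0.674 with an estimated correlation), and fatty acid synthesis 1 of 14, also over the list alone (camera adjusted p = 0.0113; adjusted p = 0.605 with an estimated correlation). The fatty acid call ended with a mean CPM of at least 5, without the libraries of number 1, and without stimulated 1 (median -0.37) or Torin 1 (-0.27). Of 18 unfolded protein response genes 2 fell, also over the list alone (camera adjusted p = 0.0107; adjusted p = 0.84 with an estimated correlation), a call that ended with library totals, without the libraries of number 1, and without stimulated 4 (median -0.13) or Torin 3 (-0.15). Of 13 heat-shock genes 1 fell (3 adjusted over the list alone; camera adjusted p = 0.0107; adjusted p = 0.451 with an estimated correlation), a call that ended with a mean CPM of at least 5. Of 22 effector genes 1 fell (Prf1) and 1 rose (Eomes, 2.01), also over the list alone (camera adjusted p = 0.0166; adjusted p = 0.674 with an estimated correlation). The effector call ended with a mean CPM of at least 5, with the replicate block (median -0.99, adjusted p = 0.104) and without stimulated 4 (-0.66) or Torin 3 (-0.92). The call for Eomes ended without Torin 1 (1.99), Torin 3 (2.12), Torin 4 (1.92) or stimulated 3 (1.9).

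Naive and quiescence genes were higher with Torin, with 5 of 22 that rose (7 rose and 1 fell adjusted over the list alone; camera adjusted p = 6.67e-05; adjusted p = 0.605 with an estimated correlation). FOXO-activated genes had 5 of 20 that rose (6 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.000169; adjusted p = 0.436 with an estimated correlation). Ccr7 belongs to both lists. Cytosolic ribosomal protein genes had 4 of 40 that rose (15 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.000545; adjusted p = 0.846 with an estimated correlation), with a median log2 change of 0.27, a call that ended without the libraries of number 1. Granulocyte markers (camera adjusted p = 0.0257; adjusted p = 0.861 with an estimated correlation) and monocyte and macrophage markers (camera adjusted p = 0.0323; adjusted p = 0.846 with an estimated correlation) were lower as lists, with 0 members past the threshold in edgeR. Both calls ended with the replicate block (adjusted p = 0.327 and 0.321), with a mean CPM of at least 5, without the libraries of number 2 and without stimulated 2 (medians -0.13 and -0.19). The granulocyte call also ended without Torin 3 (-3.11), and the monocyte call without Torin 1 (-1.71) or the libraries of number 1.

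The other lists were not past the threshold with Torin. In this comparison 4.6% of all genes passed, and edgeR recovered 11% of simulated 2-fold changes. Few or no calls in a list thus do not show a lack of change. Ribosome biogenesis genes had 0 of 34 past the threshold (median -0.21, camera adjusted p = 0.0584). That list's call began without naive 1 (-0.21), naive 3 (-0.21), naive 4 (-0.21), stimulated 2 (-0.27) or Torin 1 (-0.24). Activation genes had 2 of 22 that rose (median 0.46, camera adjusted p = 0.0717), and their call as higher began without naive 1 (0.46) or naive 3 (0.46). Translation factors had 7 that rose and 2 that fell of 26 (camera adjusted p = 0.18). Map1lc3b, an autophagosome gene, rose from 138 ± 18.6 to 300 ± 24.1 CPM and was 1 of 2 lysosome and autophagy genes of 29 that rose. In the p53 and apoptosis list 2 of 17 rose and 4 fell, and among 22 mTOR pathway components 1 rose and 1 fell (Eif4ebp1). The mitochondrial ribosome and import list had 2 of 24 that fell, G1/S and DNA replication 1 of 36, nonsense-mediated decay factors 1 of 16, and other splicing regulators 2 of 36 that rose. Inhibitory receptors, mitosis, mitochondrially encoded transcripts and SR splicing factors had 0 members past the threshold. The inhibitory receptor list had a median of -0.15. Its member Lag3 was higher without passing, at 206.6 to 223.5 CPM in Torin against 72.1 to 122.5 CPM in stimulated libraries. Calls as lower began for G1/S and DNA replication without stimulated 3 (-0.39) or Torin 4 (-0.44) and for mitosis without Torin 4 (-0.75). Neither B cell, dendritic cell, erythroid and platelet, CD4, NK nor stromal markers had a member past the threshold. Without Torin 4 the dendritic cell (-0.65) and erythroid and platelet (-0.64) lists passed as lower.

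**Figure D2:**
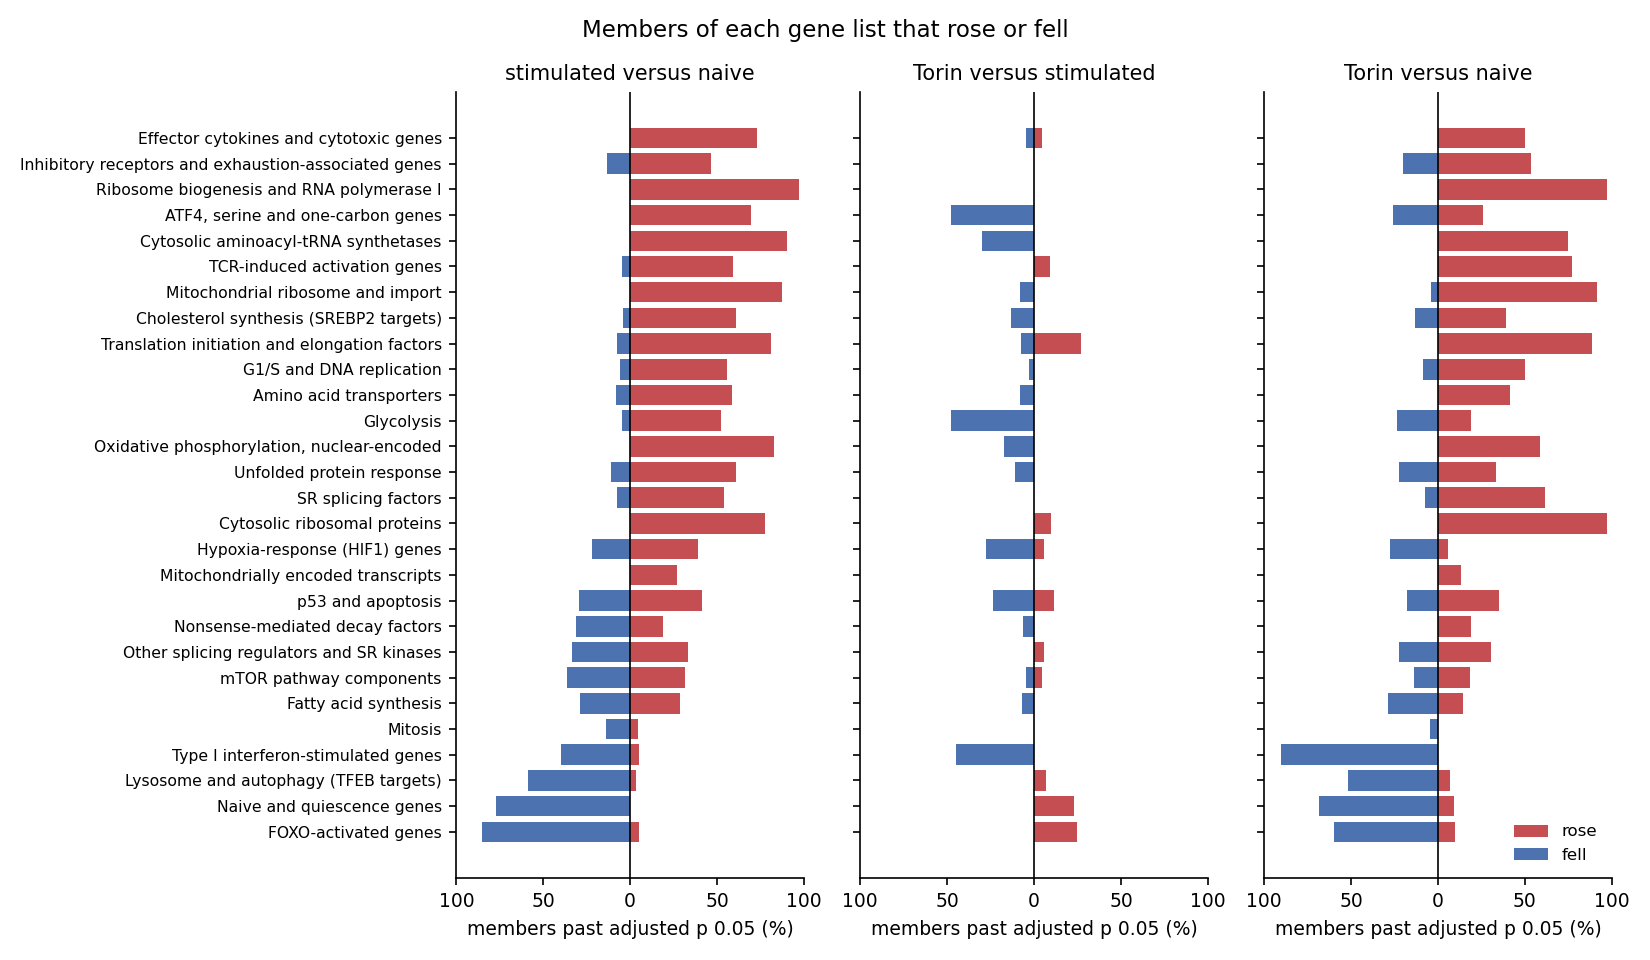
Percent of the measured members of 28 gene lists that rose (right) or fell (left) in each of the 3 comparisons, by the gene test over all genes. Ribosome biogenesis has 33 of 34 members that rose in stimulated against naive cells. In Torin against stimulated cells it has 0 past the threshold, where 4.6% of all genes passed.

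The changes with Torin were then set against the stimulation response, in comparisons that share the stimulated libraries. Of the 4272 genes that rose with stimulation, 342 (8.0%) fell with Torin, against 98.4 for independent calls, and 37 rose further, against 98.9. Of the 4501 that fell, 353 (7.8%) rose with Torin, against 104.2 for independent calls, and 73 fell further, against 103.6. Genes that moved back made up 67.7% of the 1027 genes changed with Torin. By list, 8 of the 16 ATF4, serine and one-carbon genes that rose with stimulation moved back, as did 6 of 11 glycolysis genes, 5 of 7 hypoxia-response genes, 6 of 18 aminoacyl-tRNA synthetase genes and 0 of 33 ribosome biogenesis genes. Sharing these libraries makes the changes of both comparisons oppose each other. Across 22238 genes, which are not independent replicates, the log2 changes correlated at r = -0.33 (Spearman -0.32), against -0.45 on average in data simulated with no effect. The value of r also depends on the size of the stimulation effect, which the simulated data lack, so these values are not on 1 scale. The covariance was -1.27, against -0.68 on average in the simulated data (-0.74 to -0.64), and averaged -0.62 with the stimulated libraries split. With the stimulated libraries split between the comparisons, r averaged -0.11 (-0.18 to -0.05) and the share moved back averaged 3.1% (1.2 to 5.5), against 7.9% with all libraries. Genes that moved back then made up 60.2% (46.6 to 74.3) of those changed with Torin. Genes that rose with stimulation and fell with Torin averaged 111.7, against 30.8 for independent calls, and the reverse 102.5 against 26.6. Genes that rose further averaged 14.3, against 27.7 for independent calls, and genes that fell further 36 against 29.7. The share moved back was 1.1% without Torin 3, 2.2% without Torin 1, 4% without Torin 4, 4% without stimulated 2 and 3.9% without stimulated 4 (share of stimulation-changed genes moved back by Torin).

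The last comparison set Torin against naive cells. Of 22 activation genes, 17 were higher in Torin than in naive libraries and 5 were not past the threshold (18 higher adjusted over the list alone; camera adjusted p = 2.92e-12; adjusted p = 0.11 with an estimated correlation). Myc was 433 ± 4.09 against 30.1 ± 15.8 CPM (log2 change 3.85, SE 0.37, adjusted p = 5.55e-05) and Il2ra 190 ± 23.9 against 8.17 ± 8.25 CPM. Lag3, an inhibitory receptor gene, was 215 ± 8.46 against 4.77 ± 4.48 CPM and the calcium sensor gene Ncs1 19.4 ± 1.89 against 0.37 ± 0.28 CPM. S1pr1, whose product lets T cells leave lymph nodes, was lower, at 1.04 ± 0.21 against 196 ± 47.9 CPM, as was Cd7, at 1.9 ± 1.06 against 483 ± 223 CPM. Ccr7 was higher, at 1285 ± 136 against 352 ± 52.2 CPM. Il2 was higher, at 74.2 ± 35.1 against 10.1 ± 11.5 CPM (adjusted p = 0.0179). Ifng was not past the threshold (3.02, adjusted p = 0.0761) but passed without naive 1 (4.53). Total Tra2b was higher, at 151 ± 4.73 against 100 ± 9.69 CPM (0.59, SE 0.14, adjusted p = 0.00723), but was not past the threshold with library totals alone. The largest falls included Hp, Retnlg and Fpr1, genes of granulocytes that followed naive 2. The calls for Hp without Torin 1 (-8.28), Torin 3 (-9.88) or Torin 4 (-7.94) and for Fpr1 without naive 2 (-4.44), Torin 1 (-8.39), Torin 3 (-8.19) or Torin 4 (-7.46) ended. The call for Retnlg ended without naive 2 (-5.23), Torin 1 (-8.16), Torin 3 (-8.20) or Torin 4 (-9.56).

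Between Torin and naive cells 7163 genes changed, 3648 higher and 3515 lower, 2489 and 2904 at least 2-fold. With library totals alone 33.4% of changed genes were higher, against 50.9%. By camera 19 of 37 lists passed, 13 higher and 6 lower, and 0 with an estimated correlation (lowest adjusted p = 0.11). Ribosome biogenesis had 33 of 34 that rose, also over the list alone (camera adjusted p = 1.86e-35; adjusted p = 0.11 with an estimated correlation), with Polr1b at 16.3 ± 2.35 against 1.83 ± 0.46 CPM. Cytosolic ribosomal proteins had 39 of 40 that rose, also over the list alone (camera adjusted p = 1.35e-15; adjusted p = 0.237 with an estimated correlation). Type I interferon-stimulated genes had 18 of 20 that fell (19 adjusted over the list alone; camera adjusted p = 7.82e-10; adjusted p = 0.237 with an estimated correlation), with Ifit3 at 0.11 ± 0.14 against 16.2 ± 2.72 CPM. Glycolysis had 4 that rose and 5 that fell of 21 (4 and 6 adjusted over the list alone; camera adjusted p = 0.703), and ATF4, serine and one-carbon genes 6 and 6 of 23 (7 and 6 adjusted over the list alone; camera adjusted p = 0.897). Granulocyte markers (camera adjusted p = 0.00727; adjusted p = 0.637 with an estimated correlation) and monocyte and macrophage markers (camera adjusted p = 0.00396; adjusted p = 0.571 with an estimated correlation) were lower as lists. Both calls ended with a mean CPM of at least 5, as did those of SR splicing factors (camera adjusted p = 0.00761) and heat-shock genes (camera adjusted p = 0.0294), which also ended with library totals. SR splicing factors (median 0.55) and heat-shock genes (median -0.41, with 5 that rose and 1 that fell of 13) had been called as higher. With an estimated correlation their camera adjusted p was 0.316 and 0.339.

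The splicing comparisons asked how Tra2b transcripts with the poison exon, an ultraconserved exon whose inclusion marks the transcript for decay, were used. In GENCODE M21, 3 annotated Tra2b transcripts carry an internal exon wholly inside the first coding intron. Most of their counts belonged to Tra2b-206 (ENSMUST00000162413), a decay-annotated transcript of 10 exons and 1687 nt with a poison exon of 276 nt. The poison exon share of Tra2b counts was 67.8% ± 1.7 (SD, n = 4) in naive, 45.0% ± 0.6 (n = 4) in stimulated and 53.5% ± 4.9 (n = 3) in Torin libraries. These are shares of estimated counts, not corrected for transcript length, and exon inclusion itself was not measured from reads. The groups did not overlap, at 65.5 to 69.2%, 44.4 to 45.6% and 48.0 to 57.3%. The share was 22.7 points lower in stimulated than in naive libraries, 8.5 points higher in Torin than in stimulated libraries, and 14.2 points lower in Torin than in naive libraries. Each 2-sided exact permutation p was 0.0286, the smallest that 70 or 35 assignments allow, and 0.0286 adjusted over the 3 comparisons. These tests take the libraries as unpaired, and an exact test of pairs by number has too few pairs to pass. Summed poison exon transcripts were 67.9 ± 6.4, 56.2 ± 7.94 and 80.9 ± 9.72 CPM in naive, stimulated and Torin libraries. Protein-coding transcripts were 26.8 ± 4.91, 66.6 ± 9.08 and 65.9 ± 5.73 CPM. Coding transcripts were higher in stimulated than in naive libraries (log2 ratio 1.31, exact permutation p = 0.0286) and differed little between Torin and stimulated libraries (-0.02, exact permutation p = 0.886). Poison exon transcripts were higher with Torin than in stimulated libraries (0.52, exact permutation p = 0.0286), and had a log2 ratio of -0.27 with stimulation (exact permutation p = 0.0571). With library totals alone these ratios were 0.68 and -0.77 (exact permutation p = 0.0286 for both), and those of coding transcripts 0.81 with stimulation (exact permutation p = 0.0286) and 0.14 with Torin (exact permutation p = 0.257). The size of these changes thus depended on the scaling, and so did whether poison exon transcripts passed with stimulation.

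**Figure D3:**
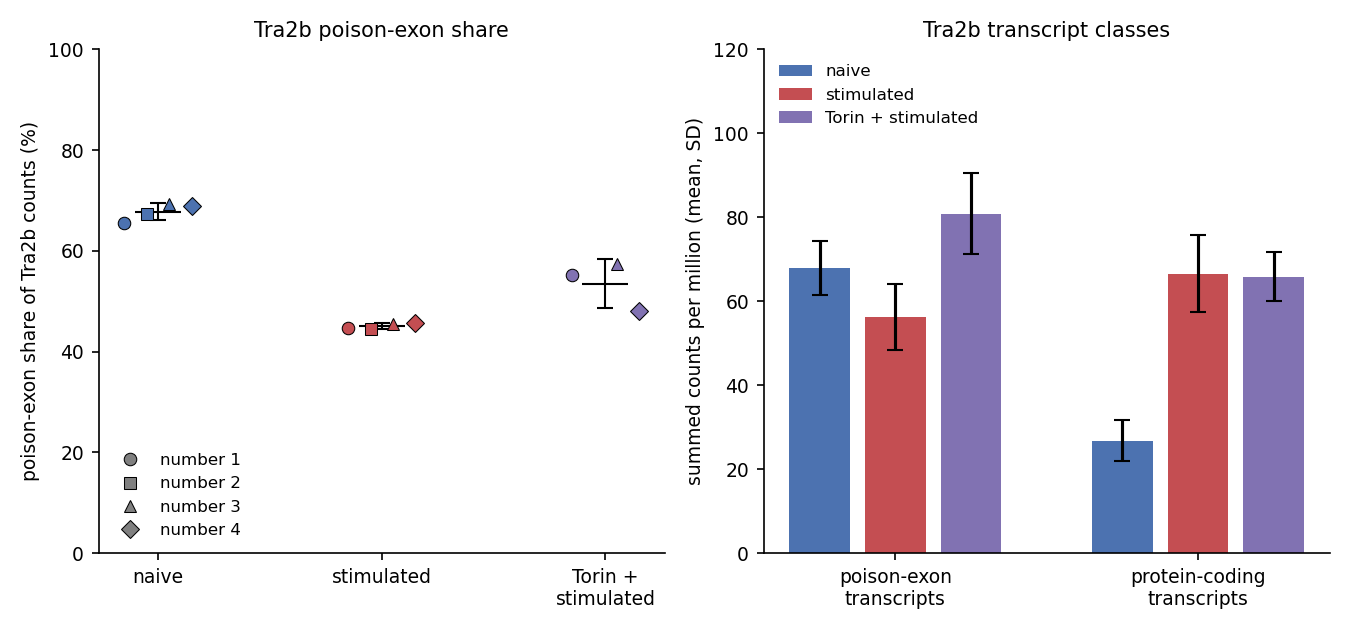
Left, poison exon share of Tra2b counts (%) in each library, by group, with markers by replicate number and mean ± SD. Right, summed CPM of poison exon and protein-coding Tra2b transcripts per group (bars, mean; whiskers, SD), with coding transcripts at 26.8 CPM in naive and 66.6 CPM in stimulated libraries.

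The coding transcript Tra2b-204 (ENSMUST00000161286, 3403 nt) held 26.7% ± 3.7 of Tra2b counts in naive, 53.3% ± 0.7 in stimulated and 43.8% ± 5.3 in Torin libraries. Tra2b-206 held 65.3% ± 4.6, 44.0% ± 1.0 and 51.9% ± 5.6. The last exon has 2318 nt in Tra2b-204 and 405 nt in Tra2b-206. Whether coverage of these last exons moved estimated counts between both transcripts was not tested. The share of counts in transcripts annotated as decay targets or retained introns was also taken for the 13 SR splicing factor genes, the family of Tra2b. In stimulated against naive cells it was lower for 8 of 13 genes, Srsf1, Srsf2, Srsf3, Srsf5, Srsf7, Srsf9, Tra2a and Tra2b, each with an adjusted exact permutation p of 0.0464. Srsf7 went from 49.6% ± 11.3 to 13.3% ± 0.7, Srsf3 from 51.1% ± 4.5 to 29.7% ± 2.5 and Tra2a from 91.8% ± 11.8 to 51.8% ± 5.1. With decay-annotated transcripts alone, 0 genes passed (6 at an unadjusted exact p under 0.05, lowest adjusted p = 0.0619). In each comparison the lowest exact p possible is 0.0286, so after adjustment a gene passes only if many genes reach that floor together. Counts of genes that passed are thus no verdict on single genes. In Torin against stimulated cells 0 of 12 genes passed by the exact test (3 unadjusted, lowest adjusted p = 0.114), with 9 higher and 2 lower. Srsf7 stood at 19.9% ± 2.6 against 13.3% ± 0.7, and Tra2b at 55.3% ± 5.5 against 46.1% ± 0.6. Against naive cells 0 of 12 passed with Torin (4 unadjusted, lowest adjusted p = 0.0857), with 10 lower.

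**Figure D4:**
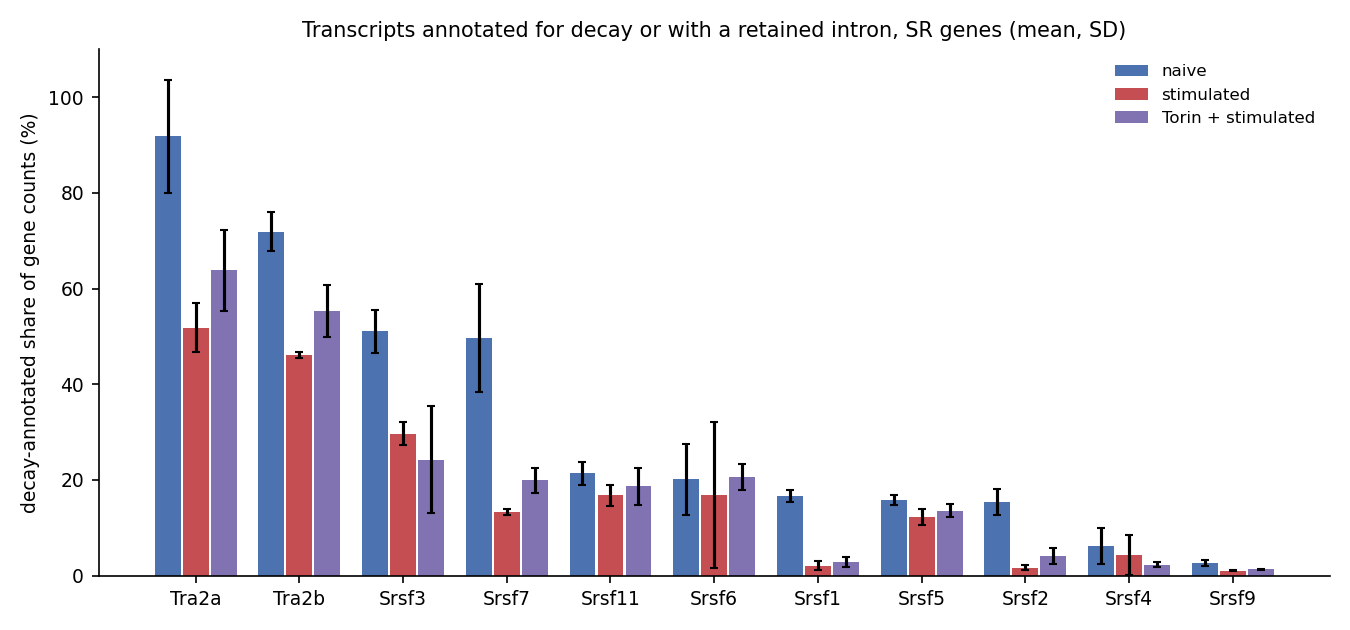
Share of counts (%) in transcripts annotated as decay targets or retained introns for 11 SR genes (bars, mean; whiskers, SD; n = 4 naive, 4 stimulated, 3 Torin). Srsf7 goes from 49.6% in naive to 13.3% in stimulated and 19.9% in Torin libraries.

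As genes, SR splicing factors had 7 of 13 that rose and 1 that fell with stimulation (9 and 1 adjusted over the list alone; camera adjusted p = 0.0133; adjusted p = 0.361 with an estimated correlation), a call that ended with library totals (median 0.26, against 0.72) and with a mean CPM of at least 5. Srsf3 rose from 171 ± 36.0 to 885 ± 159 CPM and Srsf7 from 113 ± 34.9 to 386 ± 11.6 CPM, while Srsf5 fell from 365 ± 59.1 to 183 ± 9.49 CPM. Of 36 other splicing regulators and SR kinases 12 rose and 12 fell (13 and 12 adjusted over the list alone; camera adjusted p = 0.967). Hnrnpa1 rose from 79.0 ± 19.7 to 368 ± 34.5 CPM, and the SR kinase gene Clk1 fell from 87.6 ± 9.94 to 21.4 ± 2.16 CPM. Of 16 nonsense-mediated decay factors 3 rose and 5 fell, also over the list alone (camera adjusted p = 0.285). Magoh, of the exon junction complex, rose from 179 ± 18.0 to 1053 ± 203 CPM, and Upf2 fell from 13.3 ± 1.35 to 7.06 ± 1.16 CPM.

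Relative transcript use was tested in 10224 genes with 42698 transcripts. It changed in 403 genes with stimulation and in 137 with Torin against stimulated cells by diffSpliceDGE, or in 246 and 35 with the replicate block. A limma test of transcript ratios, added after simulated data showed many false calls, gave 4244 and 100 genes, of which 250 and 10 were shared. With Torin the limma count was 10 with the replicate block and 35, 23, 11 and 20 without the libraries of numbers 1 to 4. With only the libraries compared it was 8, and up to 14 in other splits of the same libraries. A stricter transcript filter left 82 and 23 genes by diffSpliceDGE. Psmb10, an immunoproteasome subunit gene, had 94.3% ± 1.0 of its counts in Psmb10-201 in naive and 46.3% ± 7.9 in stimulated libraries (exact permutation p = 0.0286). Ccm2-201 went from 69.0% ± 5.0 to 98.9% ± 0.6 of Ccm2. Lancl1-201 went from 23.2% ± 9.6 to 68.2% ± 9.5 with stimulation and stood at 29.1% ± 8.3 with Torin. By limma on ratios Lancl1 passed with stimulation (adjusted p = 0.00404) but not with Torin against stimulated cells (adjusted p = 0.133). Zfp746-201 held 64.3% ± 4.4 in stimulated and 2.3% ± 4.0 in Torin libraries. Ptprc, whose isoforms mark T cell activation, was not past the threshold by diffSpliceDGE (adjusted p = 1 in both comparisons), nor was Tra2b (adjusted p = 0.831 and 1). With stimulation limma called both Ptprc (adjusted p = 0.0416) and Tra2b (adjusted p = 0.00066), and with Torin neither (adjusted p = 0.457 and 0.558). The genes with changed transcript usage, Torin versus stimulated, numbered 82 without Torin 1, 68 without Torin 3 and 88 without Torin 4. The genes with changed transcript usage, stimulated versus naive, numbered 256 without naive 3, 258 without naive 4, 259 without stimulated 3 and 266 without stimulated 4.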

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

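The tests of interferon-stimulated genes and of naive 1 were chosen after their results were seen, and those of the Tra2b share before. Among 150 groups of 4 libraries, 12 held a library far from the other 3 of its group, and chance flags about 1 in 20 groups. In naive libraries these were Rpl31-ps3 in naive 4 (4.44 CPM, others 20.1 to 27.3), Mtor in naive 4 (8.52, others 6.52 to 6.68), Hk2 in naive 3 (2.05, others 8.49 to 11.2), Slc7a5 in naive 1 (11.7, others 7.82 to 8.39) and Retnlg in naive 2 (206, others 4.56 to 7.57). In stimulated libraries they were Rpl31-ps3 (1.28, others 0 to 0.0179), Lrrc6 (1.15, others 0) and Klf2 (66, others 2.54 to 3.47) in stimulated 1, Trp53inp1 in stimulated 2 (3.66, others 8.51 to 10.1), Cd8b1 in stimulated 3 (188, others 313 to 339), and Myb (0.62, others 2.2 to 2.26) and Chac1 (13.3, others 37 to 45.5) in stimulated 4.

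Naive 1 held activation transcripts such as Ifng and Gzmb, and stimulated 1 held naive transcripts such as Klf2. Over 28 genes, the excess in naive 1 was a median 9.45% of the level in stimulated 1 (quartiles 7.98 to 10.66), and over 36 genes stimulated 1 held 7.68% of naive 1 (6.19 to 8.66). The ratio of the quartiles was 1.34, which argues against weak activation of all naive cells, which would raise genes unevenly. A fixed share of stimulated RNA or cells in naive 1 could give this ratio, and the Spearman correlation of these genes was 0.986 with stimulated 1 and 0.845 with stimulated 2, the next highest. Naive 2 held a median 4.6% of stimulated 2 (quartiles 2.23 to 8.42), and whether cells, RNA or reads were mixed was not tested.

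The lower poison exon share of Tra2b in stimulated cells was weighed against general shifts. In 350 genes with coding transcripts that differ at least 2 times in length, the longer lost a median 2 points of share (-2, interval -3.2 to -0.6), against 25.8 points gained by the coding transcript Tra2b-204 in its share of the sum with the main poison exon transcript, which argues against a general gain of longer transcripts. The share of decay-annotated and retained-intron transcripts changed by a median -0.5 points (-0.6 to -0.5) in 3809 genes outside the SR list, of which 69.5% were lower, by -0.9 in 31 other splicing regulators (23 lower) and by -13.7 in 11 SR genes (11 lower). A loss in most genes was thus present. Its size in points cannot decide whether a general loss is the cause, as starting shares were not matched. A gene that starts low can lose few points, while SR genes started at up to 91.8% (Tra2a). Both intervals resample genes, not libraries. A change in splicing or decay that centres on SR genes may also explain the pattern, and a general loss, splicing and decay were not told apart.

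Interferon-stimulated genes were lower with Torin than in stimulated cells by camera (adjusted p = 5.56e-14), but not past the threshold with an estimated correlation (adjusted p = 0.317). For lists in this comparison chance cannot be excluded, as 3 of 35 splits gave as many. The median log2 change of the list was -1.79 without the libraries of number 2, where myeloid transcripts were high, and -2.1 with library totals alone. These values argue against myeloid cells in stimulated 2 and against composition factors as the cause. Summed monocyte and macrophage markers were 110.6, 99.6 and 204.1 CPM in stimulated 1, 3 and 4, against 49.3, 57.1 and 86.1 CPM in Torin 1, 3 and 4. Myeloid cells in those libraries were not tested as a cause. An effect of Torin on interferon signalling may explain it if the fall is real, but no such effect was tested.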

How the results depend on the processing

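Removal of a number, removal of genes at 0 in 1 library of a group, the limma ratio test and library totals for summed Tra2b transcripts were added after the data were seen; the others were planned. For stimulated against naive and Torin against naive cells, counts of changed genes stayed within 1.5 times under each alternative. For Torin against stimulated cells 1027 genes became 656 with no filter, 675 with the prefix, 159 against 0.5 log2, 2970 by DESeq2, 191, 338, 14 and 55 without numbers 1 to 4, and 144 (without Torin 3) to 1058 with 1 library left out, where fewer libraries were fitted. For the other settings the cause was not tested. Lists past the threshold were 0 in each comparison with an estimated correlation, against 21, 16 and 19, and 18 to 24, 11 to 20 and 15 to 23 otherwise. With a mean CPM of at least 5 the calls of 3, 5 and 4 lists ended. With library totals Tra2a, stimulated versus naive, reversed from 0.03 to -0.45 and began to pass. Tra2b, stimulated versus naive, changed sign from 0.32 to -0.19 but passed in neither, which was counted as the same. The median of all genes shifted from -0.22 to -0.71. Of calls for named genes over the alternatives, 8344 were the same, 791 weaker, 61 stronger and 1 reversed. For Torin against stimulated cells, 39 named genes were weaker against 0.5 log2, 14 with the prefix, 10 with library totals, 10 with no filter, and 44, 31, 56 and 52 without numbers 1 to 4. With stimulation at most 16 were weaker in any of these settings. Among other changes, the replicate block ended the calls of Cd163 with stimulation and of Ccl1, Slc16a3 and Orc1 for Torin against naive cells, where it began Mki67. For Torin against stimulated cells it ended Chac1, Tpi1, Pfkm, Elovl6, Hspe1, Mrpl20, Ifit3 and Cdkn1a and began Cd3e and Tcf7.

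The opposition of the Torin and stimulation effects was -0.33, -0.11 with the stimulated libraries split and -0.46 to -0.22 with 1 library left out. The share of stimulation-changed genes moved back by Torin was 7.9%, 16.1 with a mean CPM of at least 5 (fewer genes tested), 3.1 with the split, 1.9, 3, 0.1 and 0.4 without numbers 1 to 4, and 1.1 to 8.6 with 1 library left out. The Tra2b poison exon transcript share kept its direction in each alternative. With 1 library left out it passed for stimulated versus naive cells (exact p = 0.0286), while 3 against 3 or 2 against 4 libraries, as with Torin, and the pairs are too few to pass. Paired differences were -22.7 points for the Tra2b poison exon transcript share, stimulated versus naive (exact p = 0.125), 8.3 for the Tra2b poison exon transcript share, Torin versus stimulated (exact p = 0.25) and -14.3 for the Tra2b poison exon transcript share, Torin versus naive (exact p = 0.25). In that order, without numbers 1 to 4 they were -23.4, -22.6, -22.4 and -22.5 (exact p = 0.1 each), then 7.5, 8.3, 6.7 and 11.4, and -15.8, -14.3, -15.7 and -11.1. With 1 library left out they were -23.5 to -22.2, 6.6 to 11.2 and -16.2 to -11.5. SR genes past the threshold for the share of decay-annotated and retained-intron transcripts were 8 with stimulation, and 0 with nonsense-mediated decay alone, where 9 were lower and 2 higher (6 at an unadjusted exact p under 0.05). At the lowest possible exact p, 6 genes are too few to pass after adjustment.

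The genes with changed transcript usage, stimulated versus naive, were 403, 82 with the stricter filter, 1373 by the quasi-F test, 246 with the block, 248, 183 and 185 without numbers 2 to 4, and 256 to 431 with 1 library left out. Limma on ratios gave 4244, 4013 with the block, and 3220, 3149, 2895 and 2810 without numbers 1 to 4. The genes with changed transcript usage, Torin versus stimulated, were 137, 23 with the stricter filter, 35 with the block, 79, 36 and 55 without numbers 1, 3 and 4, and 68 to 157 with 1 library left out. Limma gave 100, 10 with the block, and 35, 23, 11 and 20 without numbers 1 to 4. The cause was not tested. No counting limit from depth was computed, as totals are estimates.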

Other observations

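The genes in this part were picked after their values were seen, and the tests by splits were planned before, except those of limma ratios. Some genes moved further with Torin in the direction of stimulation. Dusp5, a phosphatase of ERK kinases, went from 22.8 CPM in naive to 118 in stimulated and 360 in Torin libraries, and Orai1, a calcium channel, from 101 to 159 and 276 CPM. Eef1a1, a translation elongation factor, went from 1028 to 1314 and 2213 CPM. In the other direction, the immunoproteasome genes Psmb8 (1342, 324 and 189 CPM) and Psmb10 (285, 199 and 53.7 CPM) fell with stimulation and further with Torin, as did Ly6c2 (1150, 217 and 49.7 CPM), S100a4 (161, 38.6 and 6.93 CPM) and Lgals1 (534, 215 and 67.3 CPM). Of genes changed with Torin, 125 were higher and 97 lower with no call for stimulation.

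The libraries of number 3 expressed Xist (27, 41.7 and 45.7 CPM in naive, stimulated and Torin) and held at most 0.0856 CPM of Ddx3y, a Y chromosome gene, which stood at 3.83 to 8.85 CPM in the libraries of the other numbers. Jchain, a plasma cell gene, stood at 652, 154 and 134 CPM in the libraries of number 4 and at most 1.18 CPM elsewhere.

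Whether splits of the libraries into other groups gave as many calls was counted over 35 splits per comparison, the real one included, with only the libraries compared. For changed genes 1 of 35 splits, the real one, gave as many in each comparison, a share under 0.05. That share counts all splits alike, although libraries of the same number resembled each other. Splits that mix the groups also widen the spread within them, which lowers their counts. The real counts were 8528 (stimulated against naive), 975 (Torin against stimulated) and 7234 (Torin against naive), and the highest others 1, 1 and 0. Among the 8 splits that part as many pairs of numbers, the highest others were 0 (stimulated against naive) and 1 (Torin against stimulated). As 8 splits are too few for a share under 0.05, chance is not excluded if libraries of a number are paired. For lists past the threshold chance cannot be excluded, with 8, 3 and 13 of 35 splits giving as many. The real counts were 22, 19 and 19 and the highest others 27, 23 and 22, or 23 and 14 among the splits that part as many pairs. For transcript usage by diffSpliceDGE the real split alone, 1 of 35, gave as many with stimulation (280 genes, highest other 37). Among splits that part as many pairs the highest other was 28, with the same limit of 8 splits. With Torin against stimulated cells chance cannot be excluded (3 of 35 splits, 70 genes, highest other 88, or 65). By limma on ratios the counts were 3258 against at most 7, and 8 against at most 14.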
